A study of Mus musculus with 6 samples.

How the data were processed

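Bone marrow cells of wild-type (WT) and Tet2-/- mice, positive for CD45 and enriched for the LSK fraction (lineage-negative, SCA1-positive, CD117-positive), were profiled by CITE-seq, which counts RNA and antibody-bound tags in the same droplets. TET2 is a dioxygenase that oxidises 5-methylcytosine. All marrow was collected at 3% oxygen (physioxia). The physioxia pool stayed in the chamber, and the other pool was moved to ambient air (21% oxygen) for 1 to 6 hours. Each pool was 1 run of the 10x droplet system and held 6 mouse samples, 3 per genotype, each marked by its own hashtag antibody. Oxygen level is therefore wholly confounded with pool, lane and handling, whereas both genotypes share each lane. The panel held 5 surface antibodies (SCA1, CD117, CD150, CD48 and CD135) and 2 isotype controls (lgG2a and lgG, spelled as in the key).

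The deposited matrices hold raw counts of unique molecular identifiers (UMIs), with no normalisation, for 32285 genes and 13 antibody tags per cell barcode. The matrix header names Cell Ranger 6.0.2, whereas the submitters' notes list Cell Ranger 6.1, GRCm38 and mm10, together with FastQC, cutadapt, STAR, HTSeq and DESeq2 without saying what each was used for. The deposited key ties Hashtag1 to Hashtag3 to the WT samples and Hashtag4 to Hashtag6 to the Tet2-/- samples in both pools, and it was the only source of genotype. No column of per-sample values stayed unmapped. Gene positions came from a RefSeq table of GRCm38 matched by symbol. The series title also names bulk RNA sequencing, which was not analysed here.

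Hashtags were called with HTODemux of Seurat 5.3.0 (R 4.3.3), with centred log-ratio (CLR) counts and a positive quantile of 0.99. Singlets were kept when they had at least 500 genes and a mitochondrial UMI share under 10%. Scrublet marked 1 of 12851 cells of the physioxia pool and 6 of 9162 of the air pool, under the 0.5% set as its limit, so it was not used and hashtag doublets were the only doublets removed. The alternative without Scrublet is thus the main setting and was not run separately.

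Cells were clustered with scanpy 1.11.5 (Python 3.11.15, numpy 2.4.6, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2) on 2000 variable genes without cell cycle, hashtag and mitochondrial genes, using 30 principal components, 15 neighbours, Leiden resolution 0.8 and seed 42. Clusters took a class name from marker lists when the marker score was above 0.5 and at least 3 markers were raised. A raised marker had a UMI in at least 0.1 of the cluster's cells and a log2 fold above 0.5 over the other cells, with 5 CPM (counts scaled to library size) added. A cluster with more markers of another class among its 10 leading genes stayed unnamed. These naming limits were set after the clusters had been seen, and so the shares of the larger unnamed clusters are also given. Since genotype-dependent genes can shape clusters, the clustering was repeated without any gene called between genotypes.

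Counts were summed per mouse sample and tested with edgeR 4.0.16 (TMM factors, filterByExpr, glmQLFit and glmQLFTest) at a Benjamini-Hochberg adjusted p of 0.05. Genotype was tested within each pool as Tet2-/- minus WT, oxygen within each genotype as physioxia minus air, and the interaction as the difference between the genotype effects of the pools in a fit of all 12 samples. The same tests ran within the classes that had at least 50 cells in every sample. P-values measure the spread between mouse samples. DESeq2 1.42.0 was the second tool. Named genes are Tet2, then the 10 largest rises and 10 largest falls among called genes with a mean of at least 20 CPM in the higher group and no overlap of the samples of both groups, then up to 3 members of each list with the smallest p. A gene without a proper symbol was named only among the first 5. Other list members and any gene named outside this rule were chosen after their values were seen.

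A total of 28 gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Camera with an estimated correlation, and fry, which asks whether a list moves one way on balance without comparing it with other genes, were alternatives. No list was called in any of the 5 comparisons with an estimated correlation. For every called list the test, the median and the mean had one sign. Among lists not called these could differ, as for the NF-kB and inflammatory list between genotypes in physioxia, where the test pointed down and the median was 0.01. Calls "adjusted over the list alone" correct for the members of 1 list only.

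Class shares, phase shares and mean CLR values (natural logarithm, 1 added to each antibody count) were compared by two-sided exact permutation tests of 3 against 3 samples, which cannot give a p under 0.1. Phases were scored with scanpy on cells thinned to 4000 UMIs, which left out 1613 of 17953 cells, and also unthinned. Intervals of shares of barcodes are exact Clopper-Pearson intervals at 95% and cover counting error only.

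The sample numbers were checked for pairing on 3626 genes with a mean log2 CPM of at least 5, by correlating the deviations of each sample from its group mean. WT samples of one number correlated across the pools (0.464, 0.485 and 0.561). Within the air pool WT and Tet2-/- samples of one number correlated weakly (0.175, 0.27 and 0.204), and WT sample 1 as much with Tet2-/- sample 3 (0.179). Within the physioxia pool such samples did not pair (-0.132, -0.51 and -0.517). The fits with sample number as a block called 7503 genes for oxygen in WT against 6586 without it, and 1797 for genotype in air against 1617. In the other comparisons, whose numbers did not all pair, the block called fewer genes, as given in the part on processing.

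The tests were tried on simulated data in which 200 genes were changed. These were drawn only above a floor of mean CPM, so recovery of lower genes was not tried. Samples were simulated as independent, although WT samples correlated across the pools. At a 2-fold change the test recovered 100% of the genes between genotypes in either pool and for oxygen in WT, 91% for oxygen in Tet2-/- and 89.6% for the interaction. At 1.5-fold it recovered 73.1% (genotype, physioxia), 76.1% (genotype, air), 95.5% (oxygen, WT), 55.2% (oxygen, Tet2-/-) and 62.7% (interaction). Between 3 and 18 unchanged genes were called in a comparison.

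Alternatives were RLE factors, DESeq2, no filter on low counts, other hashtag quantiles (0.95 and a higher one), a margin rule for hashtags (a CLR difference of at least 1 between the highest and next hashtag), a stricter cell filter (1000 genes, 5%), 878 cells per sample, thinned cells, Leiden resolutions of 0.5 and 1.2, other antibody scalings, a sample number block, a fit of all 12 samples and each sample left out in turn. Chosen after seeing the data were a Scrublet score filter at 0.25, the clustering without genotype genes, the block in the list tests, leaving out samples within classes, phases and antibodies, and leaving out Tet2-/- air sample 2 with Tet2-/- physioxia sample 3, the samples that stood apart in cell loss or clusters. The groups, tests, lists, filters and the rule for named genes were fixed before the data were examined. Figures were drawn with matplotlib 3.10.9, and exact tests used scipy 1.17.1 and pandas 2.3.3.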

Results

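RNA and surface protein were counted in single CD45-positive, LSK-enriched bone marrow cells from WT and Tet2-/- mice, in 2 pools kept at 3% oxygen (physioxia) or moved to ambient air. The physioxia pool held 17378 barcodes and 213210502 UMIs, and the air pool 14626 barcodes and 172698754 UMIs. Hashtags assigned 12924 barcodes of the physioxia pool to a single mouse sample (74.4%, exact Clopper-Pearson interval 73.7 to 75.0) and 11962 of the air pool (81.8%, 81.2 to 82.4). After filtering, 17953 cells were used: 5288 from WT and 4786 from Tet2-/- samples in physioxia, and 3892 from WT and 3987 from Tet2-/- samples in air. WT physioxia samples 1 to 3 held 25555848, 29242609 and 31204019 UMIs. Tet2-/- physioxia samples 1 to 3 held 18992795, 15884941 and 33921342 UMIs. WT air samples 1 to 3 held 19712316, 25097180 and 24249868 UMIs. Tet2-/- air samples 1 to 3 held 23339907, 15512596 and 24686603 UMIs. The filter on genes and mitochondrial share removed 49.7% of the singlets of Tet2-/- air sample 2, which kept 878 cells, against 27.9% to 34.8% in the other air samples and 19.7% to 25.8% in physioxia.

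Tet2 (ENSMUSG00000040943, GRCm38 chromosome 3, 133463677 to 133545136), the targeted gene, was read first. In air its RNA was 23.9 ± 2.36 CPM in Tet2-/- and 45.2 ± 1.88 in WT samples (SD, n = 3 each), and it fell by 0.91 on the log2 scale (SE 0.08; adjusted p = 0.000471 by edgeR). In physioxia Tet2 was at 18.1 ± 3.18 CPM in Tet2-/- and 25.2 ± 2.46 in WT samples, a log2 difference of -0.49 (SE 0.14; adjusted p = 0.0608) that missed the threshold. It passed with DESeq2 (0.015), without the filter on low counts (0.0198), with the margin rule for hashtags (0.0123), with thinned cells (0.0397), in a fit of all 12 samples (0.02) and without Tet2-/- physioxia sample 3 (0.0216), and its adjusted p ranged from 0.0123 to 0.195 over the alternatives. Sequencing from the 3' end still counts transcripts of an allele that lacks other exons, so the level by itself does not test the genotype key. Within WT cells Tet2 was lower in physioxia than in air (log2 -0.89, SE 0.07; adjusted p = 5e-06), as it was in Tet2-/- cells (log2 -0.46, SE 0.14; adjusted p = 0.0406), where oxygen is confounded with pool, lane and handling. The Tet2-/- call was lost with equal cells per sample (adjusted p = 0.184) and without Tet2-/- air sample 1 (0.136), air sample 3 (0.11), physioxia sample 2 (0.0583) or physioxia sample 3 (0.0628), in a range of 0.0056 to 0.184.

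**Figure D1:**
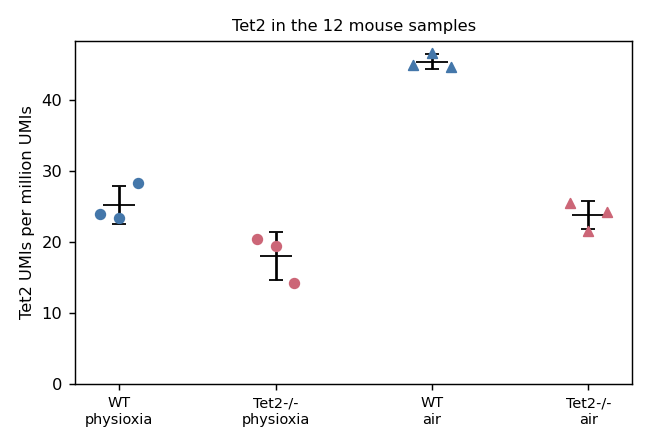
Tet2 RNA in CPM for each of the 12 mouse samples, by genotype and oxygen level. Dots are samples, lines are group means and bars are SD (n = 3). WT air samples lie between 44.7 and 46.7, and Tet2-/- air samples between 21.6 and 25.5.

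The comparison of Tet2-/- with WT cells in physioxia asked how loss of TET2 changes marrow progenitors at the oxygen level of the collection. Of 25 HSC genes 12 rose in Tet2-/- cells, beside an HSC-like share of 28.2% against 14.2% in WT cells. Procr, the endothelial protein C receptor that marks stem cells, rose from 2.64 ± 0.801 CPM in WT to 8.81 ± 1.34 in Tet2-/- samples (SD, n = 3; log2 1.75, adjusted p = 0.0036). Aldh1a1, a retinaldehyde dehydrogenase, rose from 14.5 ± 1.78 to 56.9 ± 7.35 CPM (log2 1.98, SE 0.12), Nupr1, a stress-induced regulator of transcription, by log2 2.48 (SE 0.15) and Selp, P-selectin, from 11 ± 2.63 to 36.3 ± 10.1 CPM (log2 1.71, SE 0.23). The largest named rises were those of the predicted gene Gm7324 (log2 4.07, SE 0.19), of Plscr2 (ENSMUSG00000032372, chromosome 9, 92275602 to 92297752), a phospholipid scramblase, from 2.58 ± 0.804 to 42.8 ± 5.96 CPM (log2 4.05, SE 0.20), and of Spata7, a ciliary protein gene, from 16.1 ± 3.78 to 129 ± 27.4 CPM (log2 3.01, SE 0.20). Alad, an enzyme of haem synthesis, and Ctla2b rose by log2 1.5 and 1.48.

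Among the named genes that fell in Tet2-/- cells in physioxia, Igha, the IgA heavy chain, was at 66.1 ± 47.8 CPM in WT and 3.31 ± 0.495 in Tet2-/- samples (SD, n = 3; log2 -4.35, SE 0.55, adjusted p = 0.00377), Igkc, the kappa light chain, at 90.8 ± 52.4 and 10.1 ± 2.76 (log2 -3.21, SE 0.42) and Jchain, which joins IgA and IgM units, at 23.0 ± 22.5 and 1.96 (log2 -3.66, SE 0.78). An unnamed cluster of cells with few UMIs that these genes led took similar shares of both genotypes, 8.41% ± 2.26 of Tet2-/- and 8.61% ± 0.836 of WT cells. Prss34, a basophil protease, fell by 2.64 on the log2 scale (SE 0.585), Map4k1, a kinase of lymphocyte signalling, from 41.0 ± 2.21 to 15.7 ± 2.62 CPM (log2 -1.40, SE 0.12), and Dmkn and Pbx4 by 1.84 and 1.45. The predicted gene Gm49980 fell from 26.7 ± 7.3 to 1.29 ± 0.288 CPM (log2 -4.42, SE 0.26), and Ighm by 1.52.

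By the fixed lists, 12 of 25 HSC genes rose in Tet2-/- cells and none fell (16 rose adjusted over the list alone), among them Hlf, a transcription factor of stem cells (log2 0.68), Esam (1.36) and Pdzk1ip1 (0.87). The camera test gave an adjusted p = 5.03e-09, and an adjusted p = 0.401 with an estimated correlation, under which no list was called in any comparison. Of 16 megakaryocyte genes 5 rose, including Vwf, von Willebrand factor (log2 0.86), and none fell (adjusted p = 0.00491; adjusted p = 0.401 with an estimated correlation). Of 25 immediate early genes 10 rose (16 adjusted over the list alone) and none fell, such as Nr4a2 (log2 1.11), Atf3 (0.55) and Zfp36l1 (0.67), with an adjusted p = 1.62e-08 (0.419 with an estimated correlation). Tal1 and Cd59a were the 2 of 18 erythroid genes that rose (log2 0.48 and 0.70; adjusted p = 0.00491, 0.666 with an estimated correlation). A small cluster led by Hba-a1 and Klf1, among others, held 2.58%, 1.22% and 8.0% of Tet2-/- physioxia samples 1 to 3 and 0.405% to 0.501% of WT physioxia samples. Hes1, a Notch target (log2 1.18), was the 1 of 17 TGF-beta and quiescence genes that rose (6 adjusted over the list alone; adjusted p = 0.00755, 0.561 with an estimated correlation). Among 15 p53 targets 4 rose, including Zmat3 (log2 1.0) and Ccng1 (0.47), at an adjusted p = 0.0189 (0.401 with an estimated correlation). In the interferon list 2 of 18 genes rose, among them Ifitm3 (log2 0.51), and Bst2 fell (-0.52) (10 rose and 1 fell adjusted over the list alone), at an adjusted p = 0.0145 (0.594 with an estimated correlation).

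In Tet2-/- cells in physioxia 7 of 20 myeloid genes fell (13 adjusted over the list alone) and none rose, beside a GMP-like share of 10.5% against 15.9% in WT cells. Among them were Elane, neutrophil elastase, from 2084 to 1436 CPM (log2 -0.54) and Ly86 (log2 -1.49). Within GMP-like cells 3 of the 20 rose and 1 fell, and Elane did not pass (log2 0.01). Camera gave an adjusted p = 2.88e-06 (adjusted p = 0.561 with an estimated correlation). Of 40 S phase genes 3 fell, Tyms, thymidylate synthase (log2 -0.44), Hells (-0.36) and Cdca7 (-0.27), at an adjusted p = 9.62e-08 (0.591 with an estimated correlation). Cdca3 (log2 -0.58) was the 1 of 51 G2 and M phase genes that fell (0 adjusted over the list alone; adjusted p = 0.000127, 0.666 with an estimated correlation). Of 34 nuclear genes of oxidative phosphorylation 3 fell (15 adjusted over the list alone), Ndufa1 (log2 -0.38), Ndufb2 (-0.33) and Ndufa4 (-0.29), at an adjusted p = 1.86e-07 (0.591 with an estimated correlation). Of 18 glycolysis genes 6 fell, among them Pkm, pyruvate kinase (log2 -0.65), Pfkp (-0.69) and Gapdh (-0.34), and 1 rose, the glucose transporter gene Slc2a3 (0.85), at an adjusted p = 0.00357 (0.401 with an estimated correlation). Lcn2 (log2 -1.11) fell among 4 mature neutrophil genes (adjusted p = 0.0138, 0.561 with an estimated correlation), and Igkc, Ighm and Cd79b (-0.44) among 4 mature B and plasma cell genes (adjusted p = 0.00357, 0.401 with an estimated correlation).

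The other lists were not called between genotypes in physioxia. Their adjusted p-values were 0.637 for HIF targets and hypoxia response, with Ddit4 (log2 0.52) and Bnip3l (0.30) higher and Egln1 (-0.36) lower among 21 genes, 0.937 for mitochondrially encoded genes, 0.416 for antioxidant genes, 0.285 for heat shock genes, 0.612 for NF-kB and inflammatory genes and 0.106 for TET and DNMT enzymes. They were 0.13 for lymphoid priming, in which Dntt fell (log2 -1.62), 0.276 for mast and basophil genes, in which Ms4a2 fell (-0.96), 0.21 for MHC class II, 0.0785 for autophagy, 0.275 for ribosomal proteins, 0.21 for T and NK genes, 0.0507 for monocyte genes and 0.657 for stroma and endothelium. Of 12884 tested genes 589 were higher and 507 lower in Tet2-/- cells, 1096 in all, and 31.2% of genes had groups that did not overlap, where chance gives 10%. The count was 300, 295 and 399 without WT physioxia sample 1, 2 or 3, 600 without Tet2-/- sample 1, 3536 without Tet2-/- sample 3 and 3879 with the margin rule. Named genes kept their side of the threshold in 382 of 538 combinations of gene and sample left out.

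In air, Plscr2 was the largest named rise in Tet2-/- cells, from 2.08 ± 1.06 to 31.4 ± 6.33 CPM (SD, n = 3; log2 3.88, SE 0.275), followed by Spata7 (log2 2.62, SE 0.145). Hmga2, an architectural chromatin protein of fetal stem cells, rose from 5.11 ± 0.601 to 28.6 ± 1.36 CPM (log2 2.48, SE 0.10, adjusted p = 1.5e-05), and Cd14, a co-receptor for lipopolysaccharide, from 13.0 to 65.0 ± 33.4 CPM (log2 2.33, SE 0.35). Aldh1a1 (log2 2.34), Nupr1 (2.08), Alad (1.59), Selp (1.49) and the immediate early transcription factor genes Nr4a2 (1.37) and Egr3 (1.37) completed the named rises. Klf2, a transcription factor of quiescence (ENSMUSG00000055148, chromosome 8, 72319062 to 72321654), fell from 92.6 ± 7.3 to 42 ± 6.63 CPM (log2 -1.14, SE 0.11, adjusted p = 0.000809). Apobec3, a cytidine deaminase that restricts retroviruses, fell from 55.7 to 20.3 CPM, Gadd45gip1, a mitochondrial ribosome protein, from 115 to 50.3 CPM (log2 -1.2), Map4k1 by 1.44 and Gm49980 by 4.95. Mthfsl, Gm1604a, Xylt1, Basp1 and Nr2c2ap had log2 changes between -1.42 and -1.05.

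Of 25 HSC genes 13 rose and 1 fell in Tet2-/- cells in air (17 and 1 adjusted over the list alone), with Esam (log2 1.51) and Hlf from 31.7 to 52.5 CPM (0.73), and with Hoxa9 the gene that fell (-0.33). Camera gave an adjusted p = 2.81e-07 (adjusted p = 0.509 with an estimated correlation). Erythroid genes rose in 5 of 18 (12 adjusted over the list alone), led by the globin genes Hba-a1 (log2 2.50) and Hbb-bs (1.54), at an adjusted p = 0.000169 (0.638 with an estimated correlation). The cluster led by Hba-a1 and Klf1 held 0.743%, 3.87% and 0.983% of Tet2-/- air samples 1 to 3 and 0.0971% to 0.349% of WT air samples. A total of 5 of 16 megakaryocyte genes rose, including Rab27b (log2 0.68), at an adjusted p = 0.00101 (0.56 with an estimated correlation). Cdkn1a (log2 0.32), Foxo1 (0.58) and Hes1 rose among 17 TGF-beta and quiescence genes (adjusted p = 0.0225, 0.509 with an estimated correlation). The immediate early list had an adjusted p = 0.0448 (0.638 with an estimated correlation), with Nr4a2 and Egr3 the 2 that rose and Klf2 the 1 that fell among 25. Rpl5 (log2 0.18) and Rps14 (0.16) rose and Rps2 (-0.39) fell among 28 ribosomal protein genes, called at an adjusted p = 0.0407 but not with the sample number as a block (0.101) or an estimated correlation (adjusted p = 0.77).

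Genes of oxidative phosphorylation fell in 19 of 34 in air (31 adjusted over the list alone) and none rose, with sizes such as -0.37 for Ndufa1, -0.34 for Ndufb2 and -0.28 for Uqcrq on the log2 scale. Camera gave an adjusted p = 5.18e-09 (adjusted p = 0.56 with an estimated correlation). S phase genes fell in 13 of 40 (21 adjusted over the list alone), such as Tyms (log2 -0.56), Ung (-0.53) and Mcm2 (-0.46), a subunit of the replicative helicase, at an adjusted p = 2.74e-08 (0.56 with an estimated correlation). Inflammatory genes fell in 6 of 19, among them the cytokine genes Il1b (log2 -1.59), Ccl3 (-0.99) and Tnf, from 15 to 7.89 CPM (-0.93), at an adjusted p = 0.000937 (0.509 with an estimated correlation). Within GMP-like cells 2 of 17 of them rose and 3 fell. GMP-like cells made up 17.5% of Tet2-/- and 23.0% of WT cells in air, and monocyte or dendritic cell-like cells 0.248% and 0.701%. Of 20 myeloid genes 5 fell (3 within GMP-like cells, where 1 rose), including Ly86 (log2 -1.50) and the transcription factor genes Cebpe (-0.85) and Cebpa (-0.55), at an adjusted p = 0.000891 (0.638 with an estimated correlation). Pkm (log2 -0.55) and Tpi1 (-0.39) were among 6 of 18 glycolysis genes that fell, with 1 that rose (adjusted p = 0.0153, 0.509 with an estimated correlation). Of 13 mast and basophil genes 4 fell, such as Cd200r3 (log2 -2.47) and Ms4a2 (-1.18), and Ifitm1 rose (1.02), at an adjusted p = 0.0407 (0.56 with an estimated correlation). Trbc2 (log2 -2.12) fell among 4 T and NK genes and Cd79b (-0.49) among 4 B and plasma cell genes, both lists with an adjusted p = 0.0407 (0.509 with an estimated correlation), and the latter was not called with the block (0.0613). T or NK cell-like cells numbered 1, 1 and 0 in Tet2-/- and 5, 13 and 7 in WT air samples.

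In air 835 of 12727 tested genes were higher and 782 lower in Tet2-/- cells, 1617 in all, and 35.4% of genes had groups that did not overlap, where chance gives 10%. HIF targets were not called (adjusted p = 0.763), nor were p53 targets (0.304), interferon genes (0.167), G2 and M phase genes (0.167) or TET and DNMT enzymes (0.206), among which Tet3 rose (log2 0.26) and Uhrf1 fell (-0.39). The count was 462, 627 and 979 without WT air sample 1, 2 or 3, 676 without Tet2-/- sample 3 and 734 with the margin rule. Of the combinations of named gene and sample left out, 435 of 576 stayed on their side of the threshold.

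The genotype differences of the pools overlapped. Among 12439 genes tested in both, 565 were higher in Tet2-/- cells in physioxia and 815 in air, with 362 shared where independent lists would share 37.0, and 502 and 773 were lower, with 311 shared where 31.2 would be. The pools are not independent, since WT samples of one number correlate across them, so the overlap is no replication. Klf2 was the 1 gene called in opposite directions. Calls in both pools in one direction crowded in places: of the 11853 genes with a known position, 10 of 26 tested in chromosome 9 between 85000001 and 95000000 were such calls (38.5%), among them Plscr2, Ctsh, a lysosomal protease, and Me1, malic enzyme. Further dense windows were chromosome 8 between 30000001 and 40000000 (8 of 26 genes, 30.8%, among them Gsr, glutathione reductase) and between 70000001 and 80000000 (21 of 102, 20.6%, among them Nr2c2ap and Bst2). Chromosome 8 was also dense between 65000001 and 75000000 (21 of 106, 19.8%, among them Pbx4) and between 80000001 and 90000000 (17 of 84, 20.2%, among them Gadd45gip1). In none of 1000 shuffles of gene positions was any window as full as these, a permutation p of 0.001, the smallest the shuffles can give. Within 10 Mb of Tet2, 7 of 59 genes were such calls (11.9%) against 648 of 11793 elsewhere (5.49%), an odds ratio of 2.32 (95% interval 0.884 to 5.14; two-sided Fisher's exact test, p = 0.043).

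**Figure D2:**
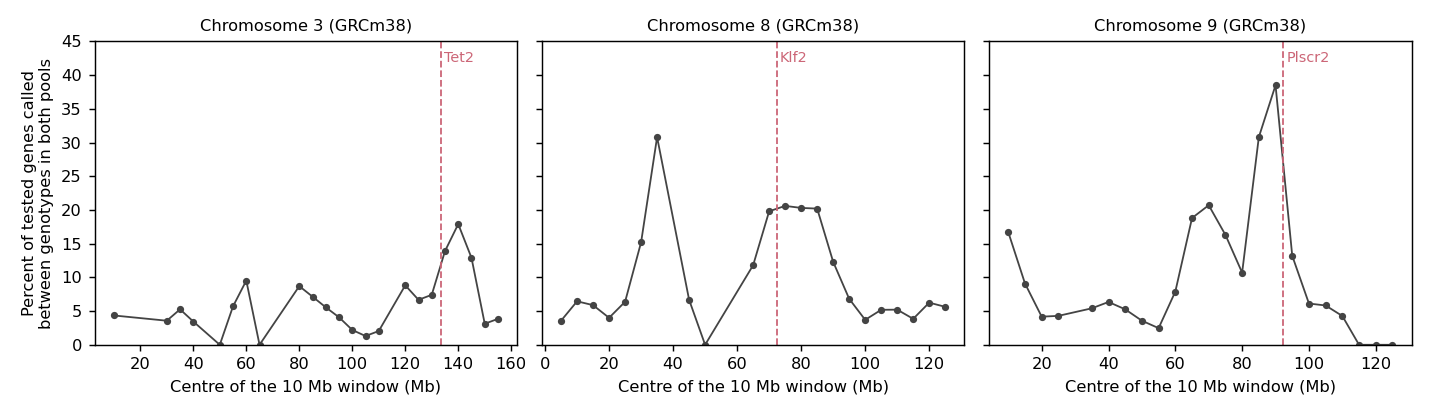
Percent of tested genes called between genotypes in both pools in one direction, in windows of 10 Mb along chromosomes 3, 8 and 9 (window centre in Mb, steps of 5 Mb, windows with fewer than 20 tested genes not drawn). Dashed lines mark Tet2, Klf2 and Plscr2. The fullest window, on chromosome 9, reaches 38.5%.

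The comparison of physioxia with air within WT cells asked what exposure to ambient air changes, with oxygen confounded with pool, lane and handling throughout. Immediate early genes were higher in the physioxia pool. Fos rose from 50.1 ± 5.06 CPM in air to 548 ± 73.1 in physioxia (SD, n = 3; log2 3.45, SE 0.10, adjusted p = 1.87e-08), Dusp1, a phosphatase that ends MAP kinase signalling, from 30.7 ± 2.43 to 294 ± 42.7 (log2 3.25, SE 0.10), Jun from 510 ± 105 to 3311 ± 110 (log2 2.70) and Egr1 from 131 ± 40.2 to 759 ± 54.3 (log2 2.54, SE 0.17). Btg2, an antiproliferative gene, rose from 50.9 to 317 ± 6.93 CPM, Zfp36, an mRNA decay factor, by log2 2.46, the chemokine gene Ccl4 from 84.1 to 556 CPM, the heat shock gene Hspa1a by log2 2.40 and the cytokine gene Osm by log2 2.39. Klf1, the master regulator of erythroid genes, rose from 3.64 to 26.2 ± 7.25 CPM (log2 2.82, SE 0.23). Lower in physioxia were Crebrf, a regulator of CREB3 proteins, from 105 ± 4.67 to 17.6 ± 0.304 CPM (log2 -2.57, SE 0.05), Bhlhe40, a transcriptional repressor, from 56.4 to 14.6 CPM, Hbp1, an inhibitor of the cell cycle, from 139 to 37.7 CPM and Prg2, eosinophil major basic protein (log2 -3.34, SE 0.63). Zswim6, Ahnak, Plaur, Luzp1, Dusp16 and Creb5 had log2 changes between -2.51 and -1.96.

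Among WT cells 19 of 25 immediate early genes rose in physioxia and 3 fell (21 and 3 adjusted over the list alone), with a list median of log2 0.94 (adjusted p = 1.81e-06; adjusted p = 0.772 with an estimated correlation). The 3 that fell were Egr3 (log2 -1.35), Klf4 (-0.60) and Nr4a2 (-0.42). All 13 mitochondrially encoded genes fell, such as mt-Nd3 from 318 to 163 CPM (log2 -0.96), mt-Nd2 (-0.73) and mt-Nd4 (-0.67), at an adjusted p = 1.81e-06 (0.772 with an estimated correlation). The median mitochondrial share of UMIs was 1.90% to 1.93% in WT physioxia samples and 2.45% to 2.59% in WT air samples. Erythroid genes rose in 16 of 18, including Gata1 (log2 1.03) and Tal1 (0.78), at an adjusted p = 0.000352 (0.772 with an estimated correlation). The erythroid-like share was 30.0% ± 1.23 of WT cells in physioxia and 25.1% ± 3.88 in air, but the class differed in makeup. An erythroid-like cluster of 954 cells with 9 markers raised, Klf1 among them, came to 96.2% from the physioxia pool. The largest erythroid-like clusters of the physioxia and air pools raised 3 and 4 markers, without Klf1. Whether the rise follows this makeup was not tested. G2 and M phase genes rose in 36 of 51, such as Kif2c (log2 1.2) and Ttk (0.78), and 2 fell (adjusted p = 2.73e-07, 0.772 with an estimated correlation), and 22 of 40 S phase genes rose, such as Fen1 (0.51), at an adjusted p = 0.00332 (0.959 with an estimated correlation). Of 25 HSC genes 11 rose, including Slamf1, which encodes CD150 (log2 1.67), and Gata2 (0.84), and 1 fell, at an adjusted p = 0.011 (0.772 with an estimated correlation). Autophagy genes fell in 12 of 17, such as the receptor gene Sqstm1 (log2 -1.13), Ulk1 (-0.68) and Map1lc3b (-0.50), at an adjusted p = 0.000918 (0.772 with an estimated correlation). These differences stand between 2 lanes.

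HIF targets were not called in WT cells (adjusted p = 0.433): 3 of 21 rose and 8 fell in physioxia against air, among them the glucose transporter gene Slc2a1 (log2 -0.94), Pfkfb3 (-0.67) and Hif1a itself (-0.53), again with oxygen confounded with lane. The NF-kB list was not called (adjusted p = 0.448) with 6 rising and 9 falling, such as Nfkb1 (log2 -1.43) and Nfkb2 (-1.42). Single members of other uncalled lists fell, such as Slc7a11, the cystine transporter (log2 -2.54), Sesn2 (-2.87), Mdm2 (-1.12), Tgfbr1 (-1.46), Xbp1 (-0.94) and Plek (-1.16), whereas Sox4 (1.2), Bcl11a (0.99), Gp5 (2.23) and Rtp4 (0.97) rose. Of 12757 tested genes 3164 were higher and 3422 lower in physioxia, 6586 in all, and 59.7% of genes had groups that did not overlap, where chance gives 10%. The margin rule gave 3568 genes.

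**Figure D3:**
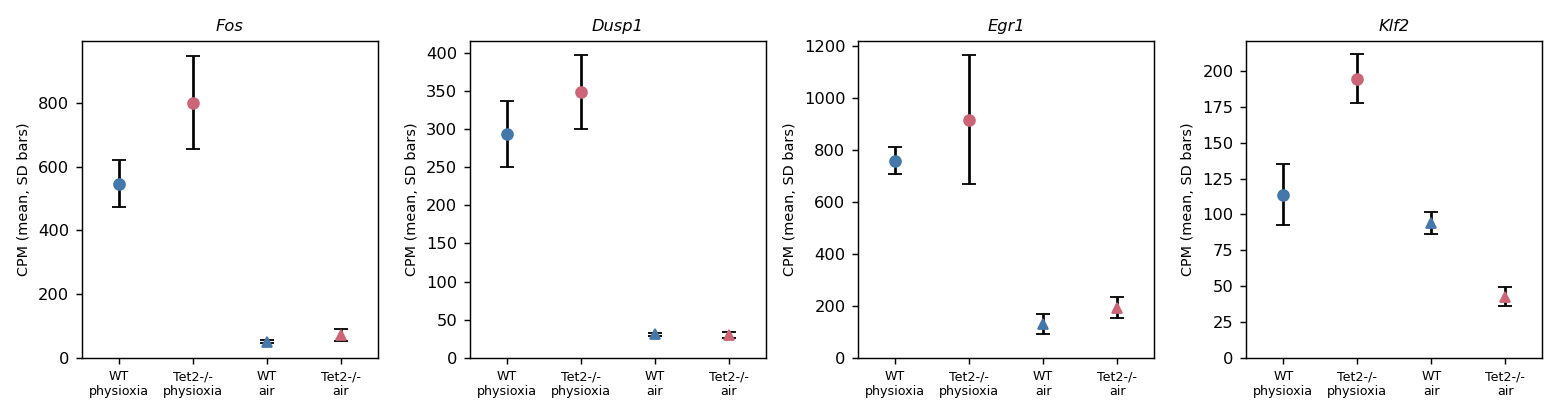
Mean CPM of Fos, Dusp1, Egr1 and Klf2 in the 4 groups, with SD bars (n = 3 mouse samples each). Fos lies at 50.1 in WT air and 548 in WT physioxia samples, and Klf2 is highest in Tet2-/- physioxia samples. Oxygen level and lane are the same division of the samples.

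In Tet2-/- cells the same comparison, with the same confounding of oxygen with lane and handling, gave Dusp1 from 30.2 to 348 ± 49.1 CPM (SD, n = 3; log2 3.52, SE 0.14), Fos from 71.6 to 800 ± 149 (log2 3.48, SE 0.21) and Jun from 500 to 4036 ± 547. Klf2 rose from 42.4 to 194 CPM (log2 2.20, adjusted p = 8.93e-05), Cd69, an activation antigen, from 57.4 to 333, and Egr1 from 193 to 914 ± 248. Ccl4 (log2 3.17), Btg2 (3.04), Osm (2.48), Zfp36 (2.46) and Hspa1a (2.31) rose as well. Emp1, an epithelial membrane protein gene, fell from 20.2 ± 4.18 to 0.765 ± 0.452 CPM (log2 -4.85, SE 0.32) and Crebrf from 115 to 22.6 CPM (log2 -2.35). Cd14 fell by 2.12 on the log2 scale, and the nuclear receptor genes Rara and Rora by 2.08 and 2.04. Zswim6, Luzp1, Morrbid, Ahnak and Fnip1, the last a regulator of AMP kinase signalling, had log2 changes between -3.16 and -1.86.

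Immediate early genes rose in 20 of 25 in Tet2-/- cells and 2 fell (22 and 2 adjusted over the list alone; adjusted p = 8.47e-10, adjusted p = 0.986 with an estimated correlation), among them Myc (log2 1.55). All 13 mitochondrially encoded genes fell, such as mt-Nd3 (log2 -1.15), at an adjusted p = 2.62e-06 (0.986 with an estimated correlation). The median mitochondrial share of UMIs was 1.93% to 2.04% in Tet2-/- physioxia and 2.58% to 2.61% in Tet2-/- air samples, and filtering removed 20.1% to 23.6% and 30.5% to 49.7% of their singlets. Interferon genes rose in 5 of 18, namely Usp18 (log2 1.83), Ifit1 (1.44), Rtp4 (1.05), Isg15 (0.94) and Ifit2 (0.74), at an adjusted p = 0.00878 (0.986 with an estimated correlation). HSC genes rose in 10 of 25, such as Pdzk1ip1 (log2 1.03) and Gata2 (0.98), and 1 fell (adjusted p = 0.0131, 0.986 with an estimated correlation). S phase genes rose in 14 of 40 (adjusted p = 0.00422), such as Cdca7 (log2 0.52), G2 and M phase genes in 11 of 51 (adjusted p = 0.0183), such as Dlgap5 (0.82), and Tal1 (0.68) in the erythroid list (0 adjusted over the list alone; adjusted p = 0.0489), all 3 with an adjusted p = 0.986 with an estimated correlation. Autophagy genes fell in 7 of 17, including Sqstm1 (log2 -0.92), at an adjusted p = 0.00878 (0.986 with an estimated correlation). HIF targets were not called (adjusted p = 0.641), with 3 that rose and 7 that fell, such as Slc2a1 (log2 -0.89) and Mxi1 (-0.69). Igkc rose by log2 2.45 in Tet2-/- cells, but was at log2 -3.10 with the margin rule.

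In Tet2-/- cells 1845 of 12633 tested genes were higher and 2340 lower in physioxia, 4185 in all, and 48.2% had groups that did not overlap, where chance gives 10%. The count was 2671 and 2677 without Tet2-/- air sample 1 or 3. Among 12398 genes tested in both genotypes, 3127 were higher in physioxia in WT and 1828 in Tet2-/- cells, with 1656 shared where independent lists would share 461, and 3357 and 2300 were lower, with 2142 shared where 623 would be. Only 4 genes were called in opposite directions, and both contrasts carry the same confounding with lane.

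The interaction asked whether the genotype difference depends on oxygen, and a lane effect common to both genotypes cancels in it. The test called 1 of 13247 genes, Klf2, with 422 genes at an unadjusted p under 0.05 and 12 called by DESeq2. Klf2 was at 94.0 ± 7.73 CPM in WT air, 42.5 ± 6.59 in Tet2-/- air, 114 ± 21.3 in WT physioxia and 195 ± 17.2 in Tet2-/- physioxia samples (SD, n = 3 each), an interaction of log2 1.93 (SE 0.19; adjusted p = 0.00247). Between genotypes Klf2 fell by 1.14 in air and rose by log2 0.78 in physioxia (adjusted p = 0.0104). The Klf2 call was lost with the margin rule (log2 2.0, adjusted p = 0.0521), in a range of 7.1e-19 to 0.0521 over the alternatives other than the sample number block. It was also lost with that block (log2 1.94, adjusted p = 0.248), whose numbers did not pair the Tet2-/- samples across the pools. Klf2 lies in one of the dense windows of chromosome 8, but is not among the calls counted there.

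For the lists, the interaction was called for immediate early genes (median log2 0.22; 3 of 25 rose adjusted over the list alone; adjusted p = 3.9e-05, adjusted p = 0.693 with an estimated correlation), NF-kB and inflammatory genes (median 0.24; 1 of 19; adjusted p = 3.9e-05, 0.607 with an estimated correlation) and G2 and M phase genes (median -0.10; 0 of 51; adjusted p = 3.9e-05, 0.987 with an estimated correlation). It was also called for T and NK genes (median 0.98; 2 of 6; adjusted p = 0.00143, 0.497 with an estimated correlation) and p53 targets (median 0.23; 0 of 15; adjusted p = 0.0265, 0.497 with an estimated correlation), and fry called no list. Apart from Klf2 no member of these lists passed the test over all genes. T or NK cell-like cells were few: 5, 13 and 7 in WT air and 1, 1 and 0 in Tet2-/- air samples. In physioxia they numbered 5, 5 and 7 in WT and 1, 2 and 4 in Tet2-/- samples. Whether the T and NK list follows these few cells was not tested.

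Clustering gave 25 clusters, most of them filled by 1 pool. HSC-like, erythroid-like, granulocyte-monocyte progenitor-like (GMP-like) and megakaryocyte-like (Mk-like) cells were numerous enough for tests within a class. The HSC-like name depends on the clustering in air, where 80.5% of these cells took the lymphoid-primed name in clusters built without genotype genes. It is also broad: the largest HSC-like cluster of the physioxia pool raised 7 of 12 HSC markers and that of the air pool 5. Only small HSC-like clusters of 122 and 36 cells raised all 12. In HSC-like cells 33 of 40 S phase genes fell in Tet2-/- samples in physioxia and 30 of 40 in air, and none rose (counted after the values had been seen, with no list test within the class), with Mcm2 at log2 -0.98 in physioxia and -1.02 in air and Tyms at -0.82 and -0.90, and higher Procr (1.27 and 1.54) and Aldh1a1 (2.26 and 2.54), these 4 called in both pools. In GMP-like cells Ly86 fell (log2 -0.90 and -1.27), Selp rose (2.06 and 1.96), Fos rose (1.31 and 0.65) and Cd14 rose in air (2.64), whereas Elane did not pass (0.01 and 0.02; adjusted p = 0.977 and 0.841). Plscr2 rose in Tet2-/- cells of all 4 classes in air (log2 3.72 HSC-like, 3.06 erythroid-like, 4.00 GMP-like and 3.65 Mk-like). Tet2 fell there too (log2 -0.67, -1.19, -0.76 and -1.21 in the same order). Fos was higher in physioxia than in air in WT cells of each class (log2 3.58 HSC-like, 4.76 erythroid-like, 2.85 GMP-like and 3.68 Mk-like), where oxygen is confounded with lane.

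Between genotypes in physioxia the tests called 1844 genes in HSC-like, 26 in erythroid-like, 1465 in GMP-like and 206 in Mk-like cells, and in air 2404, 78, 1509 and 183. For oxygen, confounded with lane, they called 3687, 4785, 4329 and 2122 genes in WT cells of these classes and 4552, 899, 3448 and 2489 in Tet2-/- cells. The interaction called 7 genes in GMP-like cells: Klf2 (log2 1.84), Rhob (1.10), Atf3 (1.06), Dleu2 (0.68), Fos (0.66), Hhex (0.52) and Tubb5 (-0.40). It called 0 by edgeR in HSC-like, erythroid-like and Mk-like cells, with 762, 262 and 496 genes at an unadjusted p under 0.05. Leiden resolution 0.5 gave 1540 genes between genotypes in physioxia and 4405 for oxygen in Tet2-/- cells in erythroid-like cells, and 2 for the GMP-like interaction. Resolution 1.2 gave 307 in HSC-like and 677 in GMP-like cells between genotypes in air, 1875 for oxygen in GMP-like Tet2-/- cells and 2 for the GMP-like interaction, and the margin rule 1523 for oxygen in erythroid-like Tet2-/- cells. Single samples moved several of these counts too. The HSC-like counts were 1214 without WT physioxia sample 3 and 1460 without WT air sample 1. The HSC-like interaction called 2 genes without Tet2-/- air sample 2 and 1 without WT physioxia sample 2 or Tet2-/- physioxia sample 1. Erythroid-like counts in physioxia were 4, 5 and 4 without WT sample 1, 2 or 3 and 4, 59 and 159 without Tet2-/- sample 1, 2 or 3. In air they were 15, 19 and 22 without WT sample 1, 2 or 3 and 221, 346 and 31 without Tet2-/- sample 1, 2 or 3. For oxygen in Tet2-/- cells they were 180, 1885 and 13 without air sample 1, 2 or 3 and 50 without physioxia sample 1. GMP-like counts were 898 without WT physioxia sample 1, 724 without WT air sample 1 and 860 without Tet2-/- air sample 1. The GMP-like interaction called 4 without Tet2-/- air sample 1, WT physioxia sample 1 or WT physioxia sample 3 and 11 without Tet2-/- air sample 3. Mk-like counts in air were 90 and 110 without WT sample 1 or 3. The Mk-like interaction called 1 without WT air sample 2 or Tet2-/- air sample 2, 3 without WT physioxia sample 2 and 2 without WT physioxia sample 3.

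HSC-like cells made up 28.2% ± 5.71 of Tet2-/- and 14.2% ± 1.81 of WT cells in physioxia and 35.8% ± 2.31 against 23.1% ± 2.88 in air (SD, n = 3; two-sided exact permutation p = 0.1 each, the smallest possible, 0.15 adjusted over 18 tests). In clusters built without genes called between genotypes the HSC-like shares were 31.6% and 21.0% in physioxia, with no overlap, but 6.2% and 3.56% in air (exact p = 0.3), where 80.5% of the HSC-like cells took the lymphoid-primed name (34.8% and 26.6%, exact p = 0.2). At Leiden resolution 0.5 HSC-like shares were 30.4% and 17.8% in physioxia but 1.13% and 0.391% in air, and at 1.2 they were 10.0% and 2.19% in physioxia and 26.2% and 10.5% in air (exact p = 0.1 each). GMP-like shares were 10.5% ± 2.19 in Tet2-/- and 15.9% ± 0.686 in WT cells in physioxia (exact p = 0.1) and 17.5% ± 4.85 and 23.0% ± 3.47 in air (exact p = 0.2; 0.277 adjusted), and with the margin rule 11.2% and 22.7% (exact p = 0.1) and 17.9% and 40.8% (exact p = 0.2). Mast or basophil progenitor-like shares were 4.95% ± 1.11 and 7.76% ± 0.924 in physioxia and 3.47% ± 1.03 and 5.66% ± 0.746 in air (exact p = 0.1 each). The groups overlapped in physioxia without genotype genes (6.12% and 7.79%, exact p = 0.2) and in air with the margin rule (3.49% and 4.75%, exact p = 0.4). Lymphoid-primed shares were 0.276% ± 0.267 and 1.47% ± 0.951 in physioxia and 1.45% ± 0.745 and 3.58% ± 2.45 in air (exact p = 0.1 each), differences of -1.19 and -2.13 percentage points that were -0.645 without WT physioxia sample 1 and -0.719 without WT air sample 1. They were 0.922% and 0.697% in physioxia in the clusters without genotype genes. Erythroid-like shares were 28.8% and 30.0% in physioxia (exact p = 0.8) and 25.0% and 25.1% in air (exact p = 1.0), but with the margin rule 25.8% and 16.0% (exact p = 0.2) and 23.8% and 13.8% (exact p = 0.3). Mk-like shares were 9.2% and 8.62% (exact p = 0.3) and 11% and 9.56% (exact p = 0.6).

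Smaller classes had T or NK cell-like shares of 0.139% in Tet2-/- and 0.321% in WT cells in physioxia and 0.0605% and 0.627% in air (exact p = 0.1 each), and monocyte or dendritic cell-like shares of 0.244% and 0.599% (exact p = 0.1) and 0.248% and 0.701% (exact p = 0.4). Unnamed clusters held 17.7% and 21.2% of cells in physioxia and 5.61% and 8.67% in air. One of them, with GMP and monocyte genes, held 4.03% ± 0.247 of Tet2-/- and 5.93% ± 1.38 of WT cells in physioxia, and one led by histone genes 4.69% ± 0.729 and 6.38% ± 0.824. Activation genes led several named clusters: Phlda1, Cd69, Btg2, Egr1 and Junb led the largest erythroid-like cluster of the physioxia pool and Bhlhe40, Relb and Nfkb1 that of the air pool.

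**Figure D4:**
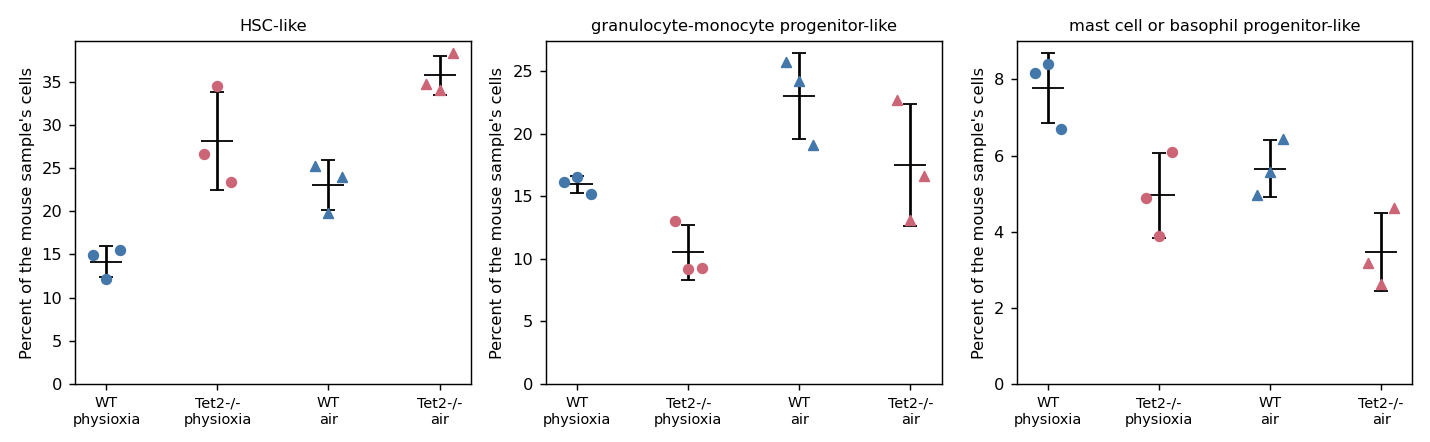
Percent of cells of each mouse sample in the HSC-like, granulocyte-monocyte progenitor-like and mast or basophil progenitor-like classes, by genotype and oxygen level. Dots are samples, lines are group means and bars are SD (n = 3). HSC-like shares run from 23.4% to 34.5% in Tet2-/- and 12.1% to 15.5% in WT physioxia samples.

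By cell cycle score, 44.9% ± 6.52 of Tet2-/- and 28.2% ± 3.55 of WT cells in physioxia fell in G1, and 55.4% ± 4.98 and 42.5% ± 2.87 in air (SD, n = 3; exact permutation p = 0.1 each, 0.12 adjusted over 12 tests). S phase shares were 18.7% ± 1.32 and 26.7% ± 1.36 in physioxia and 12.4% ± 0.138 and 18.9% ± 3.05 in air (exact p = 0.1 each). G2 and M shares were 36.5% ± 5.2 and 45.1% ± 2.2 in physioxia and 32.2% ± 5.03 and 38.7% ± 0.885 in air (exact p = 0.1 each). Within HSC-like cells G1 held 72.8% ± 0.412 of Tet2-/- and 55.1% ± 3.06 of WT cells in physioxia, and 75.6% ± 2.39 and 57.4% ± 2.03 in air (exact p = 0.1 each). Without thinning, G1 shares were 44.6% and 29.7% in physioxia and 61.4% and 49.9% in air, and S phase shares 22.3% and 31.9% and 15.3% and 25.4% (exact p = 0.1 each). The G2 and M shares were then 33.1% and 38.4% in physioxia (exact p = 0.2) and 23.4% and 24.7% in air (exact p = 0.6). Between the pools, where oxygen is confounded with lane, G1 shares differed by -14.3 percentage points in WT (exact p = 0.1) and -10.6 in Tet2-/- cells (exact p = 0.2; 0.218 adjusted). Free RNA of cycling cells can enter such scores and was not measured, so the phases by themselves do not show cycling.

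At the surface, CD48, a SLAM family protein of progenitors, was lower on Tet2-/- than on WT cells in physioxia (mean CLR 0.235 ± 0.046 and 0.374 ± 0.028, SD, n = 3; exact permutation p = 0.1, 0.156 adjusted over 28 tests). In air the values were 0.533 ± 0.121 and 0.652 ± 0.067 (exact p = 0.3), and the groups overlapped. CD48 was lower in the Tet2-/- sample of each of the 3 same-number air pairs, but such samples correlated only weakly (0.175, 0.27 and 0.204). Without Tet2-/- air sample 2 the air difference of -0.119 was -0.056. The RNA, Cd48, had log2 -0.22 and -0.36, neither called. In physioxia CD48 was at 0.74 on GMP-like and 0.12 on HSC-like cells, classes whose shares differed between genotypes. Genotypes were not compared for CD48 within classes, so its difference may in part be one of class shares. CD150, a SLAM family protein of stem cells and megakaryocytes, was at 0.812 ± 0.046 and 0.76 ± 0.02 in physioxia (exact p = 0.2) and 0.648 ± 0.077 and 0.585 ± 0.004 in air (exact p = 0.1). Its differences of 0.052 and 0.063 were 0.0254 without Tet2-/- physioxia sample 3 and 0.0184 without Tet2-/- air sample 2. CD117, the receptor KIT, was at 0.768 and 0.772 in physioxia (exact p = 0.7) and 0.657 and 0.65 in air (exact p = 0.6), whereas Kit RNA rose by log2 0.37 and 0.68. SCA1 was at -0.155 and -0.186 in physioxia and -0.123 and -0.145 in air (exact p = 0.1 each), beside a rise of its gene Ly6a of log2 1.28 and 1.34. The SCA1 difference turned with CLR across cells in both pools (-0.00433 and -0.00577), and the CD135 difference in physioxia (-0.00321). CD135, the receptor FLT3, was at -0.649 and -0.679 in physioxia (exact p = 0.1) and -0.555 and -0.586 in air (exact p = 0.3).

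Between pools, with oxygen confounded with lane and handling, CD48 on WT cells was lower in physioxia (0.374 and 0.652 in air) whereas Cd48 RNA was higher (log2 0.59, adjusted p = 0.000644). CD150 (0.76 and 0.585) and CD117 (0.772 and 0.65) were higher in physioxia, beside Slamf1 (log2 1.67) and Kit (0.32), each with an exact p = 0.1. The isotype control lgG2a moved as well, at -0.105 in physioxia and -0.241 in air on WT cells. SCA1 and CD135 lay near this background: the median was 24 UMIs per cell for SCA1 and 14 for CD135 against 26 for lgG2a in physioxia, and 25 and 16 against 23 in air. One barcode of the air pool, not among the cells used, carried 527975 UMIs of CD117.

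**Figure D5:**
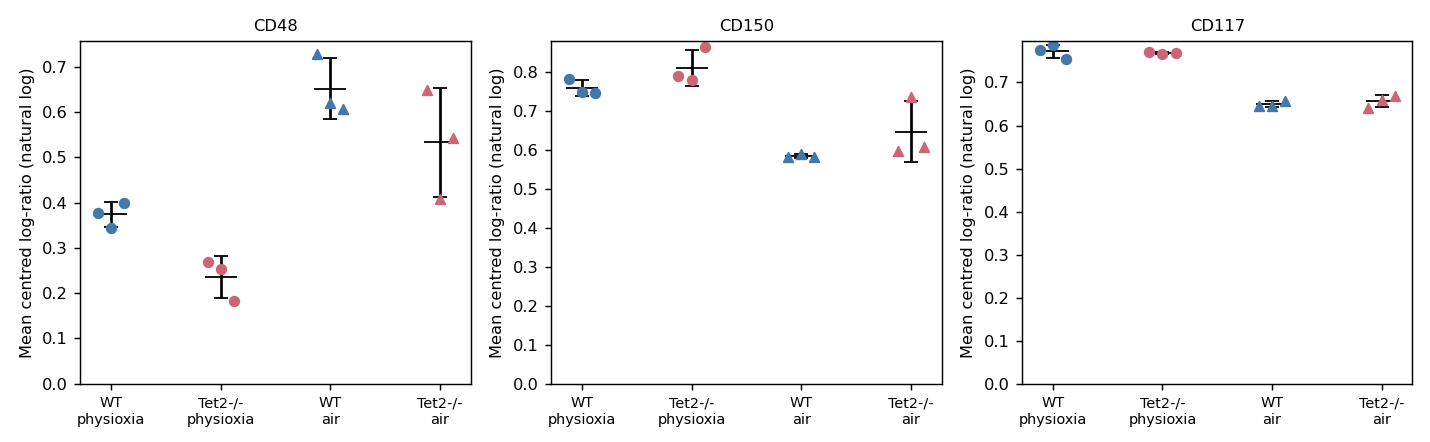
Mean CLR value (natural logarithm) of CD48, CD150 and CD117 per mouse sample, by genotype and oxygen level. Dots are samples, lines are group means and bars are SD (n = 3). CD48 means are 0.235 in Tet2-/- and 0.374 in WT physioxia samples, and 0.533 and 0.652 in air.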

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

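The test of chromosome segments away from Tet2, the changes within GMP-like cells in windows other than the fullest, the clustering without genotype genes, the clusters matched by their cells and all counts of other splits were chosen after the results they test had been seen, and the other tests before. The genotype effect differed between the pools, by a test of the difference itself, for Klf2 (log2 1.93), for 7 genes in GMP-like cells and, by camera, for 5 lists: immediate early genes (median log2 0.22), p53 targets (0.23), NF-kB and inflammatory genes (0.24), G2 and M phase genes (-0.10) and T and NK cell genes (0.98). The Klf2 call was lost with the margin rule for hashtags (log2 2.0, adjusted p = 0.0521) and with the sample number block (log2 1.94, adjusted p = 0.248). The list calls were lost with an estimated correlation (0 lists), and T or NK cell-like cells numbered at most 13 in a sample. Of 40 drawn splits of the samples, which redraw genotype within each pool, 3 gave as many interaction genes as the real 1, the real one included. The highest, with 3880 genes, exchanges the genotypes of all air samples. There the genotype effects of the pools add up, so this count of splits says nothing about Klf2.

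Genes called between genotypes in both pools crowd in stretches of chromosomes. A change in cell class shares is argued against, since in GMP-like cells in air the genes of the fullest window had a median change of 0.71 against 0.74 in all cells, 9 of 9 on the same side, and those of the chromosome 8 windows 0.64 against 0.61 (70000001 to 80000000) and 1.25 against 0.99 (30000001 to 40000000). In 1000 shuffles of gene positions no window was as full (permutation p = 0.001, the smallest the shuffles can give), so a candidate explanation is that the Tet2-/- line carries segments of another strain on chromosomes 8 and 9. Plscr2 and Mthfsl are among the calls of the chromosome 9 window, and Nr2c2ap and Bst2 among those of chromosome 8 between 70000001 and 80000000. Pbx4 and Gadd45gip1 are among those of the other dense chromosome 8 windows (65000001 to 75000000 and 80000001 to 90000000). The differences of these named genes may follow such segments and not TET2. Klf2 lies in a chromosome 8 window but was called in opposite directions in the pools, so it is not counted there. Whether a segment there bears on Klf2 was not tested and stays open. A variant carried along with the Tet2 allele stays open. The odds ratio near Tet2 was 2.32, with an interval (0.884 to 5.14) that includes 1, whereas Fisher's exact test gave a two-sided p = 0.043. An effect of TET2 on these regions was not tested.

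Immediate early genes were higher in the physioxia pool than in the air pool. Depth is argued against, since the list median in WT cells was log2 1.05 in thinned cells against 0.94. A change in the shares of these classes is argued against, since the list median was 1.29 within HSC-like, 0.59 within GMP-like, 1.06 within Mk-like and 1.53 within erythroid-like cells. Most clusters were filled by 1 pool, so cell makeup within a class was not held equal and stays open. Lane or handling of the pools cannot be told apart from oxygen, because there was 1 pool per oxygen level. Oxygen itself, the time out of the chamber and the steps before capture may each have contributed.

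The HSC-like share was higher in Tet2-/- than in WT samples in both pools. Clusters built on genes that differ between genotypes are argued against in physioxia, where the difference without these genes was 10.6 percentage points and the samples stayed apart, but stay open in air, where it was 2.64 and 80.5% of the HSC-like cells fell in clusters that took the lymphoid-primed name. In air the clusters mostly made of HSC-like cells, whatever their name, differed by 11 percentage points (40.6% and 29.6%), but they were picked with the first clustering. Hashtag calls that lose other cells stay open. The margin rule gave 12.2 percentage points in physioxia and 16.6 in air. Its shares were taken only among cells that HTODemux had called singlets, so cells lost there could not return. An effect of TET2 loss on the share of HSC-like cells may be one explanation in physioxia, and a difference in background between the mouse lines is another that was not tested. The largest HSC-like clusters of the physioxia and air pools raised 7 and 5 of 12 HSC markers, so this share need not be that of stem cells.

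For comparisons of 3 against 3 samples there are 10 splits, too few for a share under 0.05. In each of them 1 split, the real one, gave as many genes. For all cells the real counts were 1096 (genotype, physioxia), 1617 (genotype, air), 6586 (oxygen, WT) and 4185 (oxygen, Tet2-/-), and the highest other split gave 0 by edgeR in each. In the same order the real counts were 1844, 2404, 3687 and 4552 in HSC-like cells, 26, 78, 4785 and 899 in erythroid-like cells, 1465, 1509, 4329 and 3448 in GMP-like cells and 206, 183, 2122 and 2489 in Mk-like cells. The highest other split gave 0 except in GMP-like cells for genotype in air (1) and in Mk-like cells for genotype in physioxia (1) and in air (4). Unadjusted counts and DESeq2 were not run for the other splits. Every other split puts samples of both real groups on each side, so a real difference widens the spread within its sides. Low counts there are therefore no support for the real counts.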

How the results depend on the processing

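The clusters without genotype genes, the sample number block in the list tests and the samples left out within classes, phases and antibodies were chosen after seeing the data. Of 4427 combinations of named gene and setting, 4152 kept direction and side of the threshold, 168 lost the call, 105 gained it and 2 reversed. With 1 sample left out these were 2860, 332, 38 and 0 of 3230. RLE factors, DESeq2 and the other fits shifted the median of all genes by at most 0.03 (log2). For each value below the cause was not tested unless stated.

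The margin rule for hashtags, which keeps fewer cells by its construction, gave 63.3% and 66.6% singlets (physioxia, air), 3879 genes for genotype in physioxia, 734 in air, 3568 for oxygen in WT, 0 by edgeR for the interaction and 1523 for oxygen in erythroid-like Tet2-/- cells. Share differences were then 16.6 points for HSC-like (air), 9.71 and 10.0 for erythroid-like, -11.5 and -23.0 for GMP-like and -3.92 and -1.26 for mast-like cells. G1 differed by 22.7 and 24.1 between genotypes and by -8.91 for oxygen in WT. CLR differences between genotypes were -0.0218 and -0.0274 for CD117, 0.0954 for CD150 (physioxia), -0.216 and -0.241 for CD48 and 0.0585 and 0.0979 for CD135, and for oxygen in WT 0.106 for CD117 and -0.0576 for CD135. Igkc reversed for oxygen in Tet2-/- cells (log2 -3.10).

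Thinned cells reversed Phlda3 for genotype in physioxia (log2 -0.25) and gave 3 interaction lists. The sample number block gave 401 genes for genotype in physioxia, 2915 for oxygen in Tet2-/- cells and 0 by edgeR for the interaction (the Klf2 call was lost, adjusted p = 0.248, range 7.1e-19 to 0.248). Tet2 lost its call for oxygen in Tet2-/- cells (adjusted p = 0.062, range 0.0056 to 0.184) and so did the erythroid list (0.0592), while the monocyte list gained one for genotype in physioxia (0.00975). Numbers did not pair WT with Tet2-/- samples in physioxia (-0.132, -0.51 and -0.517) or Tet2-/- samples across the pools (0.701, -0.554 and -0.527). There air sample 2 went with physioxia sample 3 (0.717) and air sample 3 with physioxia sample 2 (0.594). In physioxia WT sample 2 went with Tet2-/- sample 3 (0.489) and WT sample 3 with Tet2-/- sample 2 (0.498). An exchange of Tet2-/- numbers 2 and 3 in the physioxia pool would give these pairs, but it was not tested and stays open. It would leave the groups as they are but void the block, so these lost calls say nothing of effect size. DESeq2 gave 12 interaction genes. With an estimated correlation 0 lists were called in each of the 5 comparisons, and fry called 8, 9, 12, 5 and 0 (genotype in physioxia and air, oxygen in WT and Tet2-/-, interaction).

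Leiden resolution 1.2 gave 307 genes for genotype in air in HSC-like cells, and in GMP-like cells 677 for genotype in air, 1875 for oxygen in Tet2-/- and 2 for the interaction, with share differences of 7.85 and 15.6 (HSC-like) and -5.06 (lymphoid-primed, air). Resolution 0.5 gave 1540 (genotype, physioxia) and 4405 (oxygen, Tet2-/-) genes in erythroid-like cells, 2 for the GMP-like interaction, an HSC-like difference of 0.742 in air and lymphoid-primed differences of 0 and 0, since no cluster took that name. Clusters without genotype genes gave 2.64 (HSC-like, air), -1.66 (mast-like, physioxia) and, reversed, 0.224 and 8.24 (lymphoid-primed). A hashtag quantile of 0.95 gave 70.6% and 77.4% singlets, and the higher one 75.3% in physioxia. Unthinned cells gave G1 differences for oxygen of -20.2 in WT and -16.8 in Tet2-/- cells.

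CLR across cells gave genotype differences of -0.00433 and -0.00577 for SCA1 and -0.00321 for CD135 (physioxia), all reversed. As a share of antibody counts, SCA1 was at -8.54 for genotype in air and 0.394 for oxygen in Tet2-/-, CD150 at -3.17 for oxygen in Tet2-/-, and CD135 at 0.0816 and 0.0406 for oxygen in WT and Tet2-/-, all reversed. Single cells weigh on these shares: one of WT air sample 2 held 162786 SCA1 UMIs (38.3% of that sample's antibody counts were SCA1, against 5.66% and 10.2% in the other WT air samples), and one of Tet2-/- air sample 1 held 143605 CD150 UMIs (42.8% CD150, against 26.5% and 22.2%).

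With 1 sample left out, which lowers replication, counts ranged from 295 to 3536 (genotype, physioxia; 3536 without Tet2-/- sample 3), 462 to 2313 (genotype, air), 5608 to 6278 (oxygen, WT) and 2671 to 3968 (oxygen, Tet2-/-). In HSC-like cells they were 1214 to 1647 and 1460 to 2150 for genotype in physioxia and air and 0 to 2 for the interaction, in erythroid-like cells 4 to 159, 15 to 346 and, for oxygen in Tet2-/-, 13 to 1885. In GMP-like cells they were 898 to 1299, 724 to 1413 and, for the interaction, 4 to 11, and in Mk-like cells 90 to 224 for genotype in air and 0 to 3 for the interaction. The report names the samples.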

Other observations

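Surface antibodies differed between classes. CD150 had a mean CLR of 1.05 in physioxia and 0.88 in air on Mk-like cells and 0.58 and 0.46 on GMP-like cells. CD48 was at 0.74 and 1.01 on GMP-like cells, 0.12 and 0.5 on HSC-like cells and 0.02 and 0.17 on Mk-like cells.

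A small erythroid-like cluster of 310 cells was 89.4% Tet2-/- and had a median of 43813.5 UMIs, led by Mt2, Cldn13, Hba-a1, Rhd and Klf1. It held 8.0% of Tet2-/- physioxia sample 3 (163 cells), 2.58% of sample 1 and 1.22% of sample 2, and 3.87% of Tet2-/- air sample 2 (34 cells). An HSC-like cluster of 122 cells, led by Nupr1, Sult1a1 and Procr, held 3.49% of Tet2-/- physioxia sample 3 (71 cells). Another of 36 cells was 94.4% Tet2-/- and held 3.19% of Tet2-/- air sample 2 (28 cells). The cluster led by Igha, Igkc and Jchain had a median of 1791 UMIs and came to 96.2% from the physioxia pool. No explanation was tested for these clusters.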
